A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

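The data are poly(A)-selected RNA libraries from whole cells of S. cerevisiae BY4741 and its set4∆ derivative, 9 libraries in 3 groups of 3 biological replicates. Per the labels, overnight cultures were diluted to an OD600 of 0.1 in synthetic complete medium and grown at 30 °C for 5.5 h with oxygen or 8 h under hypoxia. RNA was extracted with phenol and treated with DNase, and libraries were made with a stranded Illumina TruSeq kit and sequenced on a HiSeq2500, per the labels. Group and replicate number of each library were taken from the sample titles.

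The deposited count table holds whole-number counts of reads per feature for 7110 features, with no normalisation. The submitters' processing notes name FastQC 0.11.3, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR 3.12.1 with genome build R64, and the order of these tools, their parameters and the strand setting of the counting are not given in the sources used here. Named genes that overlap another gene are therefore given as such where they appear, and members of near-identical families (PAU genes, ribosomal protein pairs, hexose transporters) are uncertain one by one, since reads that fit several copies could be dropped or split. The deposited CPM table lists 6930 features, and each of its values equals the deposited count over the library total within a relative difference of 6.7e-09, so it carries no composition factor. It was used only for that check. Of the 7110 features, 295 were at 0 in all libraries. Feature names were matched to the R64 reference annotation, the same build by name as in the processing notes: 6048 matched by locus tag and 17 by symbol, and 1045 did not match. Coordinates are those of that reference.

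Library totals were 9183909, 9477830 and 11245019 counts for WT aerobic replicates 1 to 3, 13847248, 12570268 and 12929782 for WT hypoxia, and 13511580, 10588282 and 10367064 for set4∆ hypoxia. The 10 most abundant features took 9.69 to 13.4% of each library. Structural RNA took 0.0236 to 0.0345%, and mitochondrially encoded protein genes had 4 to 24 counts per library, so that list had no tested member and gives no result. Replicates of a group correlated with Pearson's r of 0.991 to 0.996 across genes on the log scale, and every pair of replicates differed by more than sampling noise (chi-square per degree of freedom 4.4 to 21.9), so none was treated as a copy of another.

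Counts were tested in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 5924 and removed 1186. TMM factors (0.962 to 1.045) were applied, and a quasi-likelihood model with robust dispersion estimates and 1 coefficient per group was fitted to all 9 libraries, with 6 residual degrees of freedom. The 2 comparisons were WT hypoxia against WT aerobic and set4∆ hypoxia against WT hypoxia. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested features, and a count with a log2 fold change of at least 1 in size is given beside it. Standard errors are the size of the log2 fold change over the square root of the F statistic. All adjusted p-values of single genes are from this edgeR test unless another is named.

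Gene lists (38) were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. They cover sterol synthesis and uptake, hypoxic and aerobic cell wall genes, PAU genes, isoform pairs, regulators, heme, respiration, ATP synthase, central carbon metabolism, redox balance, NAD, fatty acids, peroxisomes, oxidative and general stress. They also cover iron, zinc, phosphate, sulfur and amino acid metabolism, ribosomes, drug efflux, methyltransferases, subtelomeric genes within 20 kb of a chromosome end, meiosis, cell cycle, mating type, haploid genes, strain markers and the neighbours of SET4. The mitochondrially encoded list and the strain marker list, with 1 tested gene, were not tested as lists, which left 36. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list and with fry. Camera compares a list with all other genes. The rule for named genes took, per comparison, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap of the 3 values of each group. PAU and transposon genes are given as families. It also took up to 4 members of each list with the smallest adjusted p, and SET4, its neighbours and the marker genes.

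The overlap of the comparisons was set beside the overlap of independent lists and beside 20 simulated sets of unchanged groups that shared the WT hypoxia libraries. The procedure was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For WT hypoxia against WT aerobic (5754 genes), it recovered 76.1% of 1.5-fold, 95.5% of 2-fold and 98.5% of 4-fold changes, with 5 false calls of 185. For set4∆ against WT hypoxia (5858 genes), it recovered 92.5%, 98.5% and 100% at those folds, with 12 false calls of 206. In the data 83.9% and 53.5% of features were called in these comparisons, far more than the 200 genes changed here. These recovered and false calls therefore do not show how the procedure performs when most genes change. In a separate simulation for each comparison, only the ergosterol list was raised, by 1.5-fold. That list was called and 0 of the other lists were. Genes were drawn independently of each other, so this cannot show how the preset correlation performs where genes of a list move together. Alternatives tried were RLE factors or library size alone, no filter or a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the 6 libraries of a comparison alone, a replicate term and each library left out in turn. No sample was left out of the main fits.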

Results

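Polyadenylated RNA was sequenced from Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a, and from its set4∆ derivative, which lacks the gene of a SET-domain protein. The 9 libraries form 3 groups of 3 biological replicates: wild type (WT) after 5.5 h of aerobic growth, WT after 8 h of hypoxia and set4∆ after 8 h of hypoxia, all in synthetic complete medium at 30 °C from a starting OD600 of 0.1. Library totals ran from 9183909 to 13847248 counts, and 5924 features were tested. The first comparison asks how the WT transcriptome differs under hypoxia, and the second how loss of SET4 changes the hypoxic transcriptome. Set4∆ cells grown with oxygen were not analysed here, so the second comparison holds for hypoxia only. Levels are TMM-normalised CPM (counts scaled to the library total) with the SD of 3 libraries, and changes are log2 fold changes with standard error (SE) and adjusted p from edgeR's quasi-likelihood test.

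SET4 (YJL105W, chromosome X, 225055 to 226737 in the R64 reference) was scarce in aerobic WT cells and abundant under hypoxia. Its level was 2.37 ± 0.133 CPM (SD, n = 3) in WT aerobic libraries, 539 ± 44.7 CPM in WT hypoxia and 1.00 ± 0.192 CPM in set4∆ hypoxia. The raw counts were 20 to 27, 6278 to 7647 and 11 to 13 per library. Under hypoxia SET4 rose by 7.82 ± 0.113 (log2, SE; edgeR adjusted p = 1.15e-13), and in the deletion strain it was lower by −9.08 ± 0.124 (adjusted p = 2.26e-13), in all 3 libraries of each group. Of the genes beside it in set4∆, PAM16 rose by 0.35 (adjusted p = 0.000567), GSM1 fell by −0.30 (adjusted p = 0.0187), and neither IME2 (0.19, adjusted p = 0.305) nor YJL107C (−0.83, adjusted p = 0.242), which overlaps PRM10, passed the test. The GSM1 call was lost with library size alone as the scaling (adjusted p = 0.0543) and without WT hypoxia replicate 2 (adjusted p = 0.0776), WT hypoxia replicate 3 (adjusted p = 0.0559) or set4∆ hypoxia replicate 3 (adjusted p = 0.0703). YJL107C passed in the fit of the 6 hypoxic libraries (adjusted p = 0.0203) and without WT aerobic replicate 1 (adjusted p = 0.0135). The list of these 4 neighbours was not called in either comparison (camera adjusted p = 0.78 and 0.99).

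LEU2, URA3 and MET17, genes deleted in BY4741, had 0 counts in all 9 libraries. HIS3, of which BY4741 keeps part, was read at 64.4 ± 4.1 CPM in WT aerobic, 38.1 ± 6.3 in WT hypoxia and 73.5 ± 12 in set4∆ hypoxia (library-size CPM, SD, n = 3). The test called HIS3 lower under hypoxia (−0.79, edgeR adjusted p = 0.000286) and higher in set4∆ (0.90, adjusted p = 0.000312). The a-cell receptor gene STE2 stood at 1010 ± 29, 349 ± 15 and 1100 ± 100 CPM on the same scale, and the alpha-factor gene MF(ALPHA)1 at 1.48 ± 0.51, 12 ± 1.1 and 3.28 ± 0.59 CPM. MF(ALPHA)1 rose by 2.96 under hypoxia (adjusted p = 6.54e-08) and fell by −1.91 in set4∆ (adjusted p = 7.34e-06). Among the a markers in set4∆, STE2 rose by 1.60 (adjusted p = 5.27e-08), STE6 by 0.97 (adjusted p = 3.48e-06) and BAR1 by 0.64 (adjusted p = 1.01e-05). MFA2 rose by 0.50 (adjusted p = 0.00346), ASG7 fell by −0.48 (adjusted p = 0.00371), and AGA2 stood at −0.16 (adjusted p = 0.0672), passing without the filter (adjusted p = 0.0428) and with the 6 hypoxic libraries alone (adjusted p = 0.0374). MFA1 passed narrowly at 0.39 (adjusted p = 0.0406) and lost that call without WT aerobic replicate 2, any 1 of the WT hypoxia libraries, or set4∆ hypoxia replicate 1 or 3 (adjusted p = 0.055 to 0.147). The same call was lost without the filter on low counts (adjusted p = 0.0633) and with the 6 hypoxic libraries alone (adjusted p = 0.0807). The a marker list was called in neither comparison (6 of 7 lower and 1 higher under hypoxia, camera adjusted p = 0.059; 5 higher and 1 lower in set4∆, adjusted p = 0.12), although it passed under hypoxia with no filter (adjusted p = 0.044). SAG1, an alpha-cell agglutinin gene, stood at −0.14 in set4∆ (adjusted p = 0.0575). It passed with no filter or a stricter one, with a replicate block, with the 6 hypoxic libraries alone and without set4∆ hypoxia replicate 1 (adjusted p = 0.0333 to 0.0479). All 3 tested alpha markers rose under hypoxia and that list was not called (adjusted p = 0.059), but it passed without WT aerobic replicate 2 (adjusted p = 0.049).

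**Figure D1:**
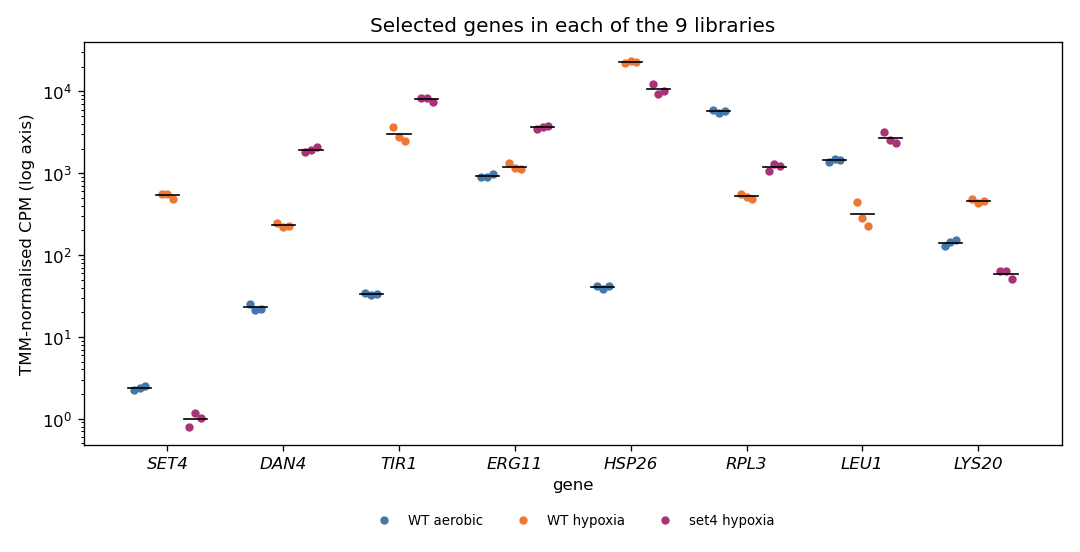
TMM-normalised CPM (log axis) of 8 genes in each of the 9 libraries, with a point per library, a line at each group mean and colour for the group. SET4 stands at 539 CPM in WT hypoxia and 1.00 CPM in set4∆ hypoxia, and DAN4 stands at 230.4 and 1938 CPM.

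In WT under hypoxia, far more of the mRNA was for anaerobic cell wall mannoproteins and stress proteins, and far less for ribosomal proteins, than in aerobic cells. Camera called these lists with the preset correlation but not with an estimated one (adjusted p = 0.32 for each). Levels are shares of a library, so the amount of mRNA per cell was not measured. DAN1, an anaerobic cell wall mannoprotein gene, rose from 1.83 ± 0.983 to 2259 ± 348 CPM (SD, n = 3; log2 10.22 ± 0.232 SE, adjusted p = 4.05e-12). HSP26, a small heat shock protein gene, rose from 40.9 ± 2.08 to 23050 ± 608 CPM (log2 9.14 ± 0.139, adjusted p = 1.36e-13). The other rises named by the fixed rule were those of SIP18, SPG4, HXT5, SPG1 and GRE1, with log2 changes from 8.65 for GRE1 to 10.16 for SIP18. YCL048W-A went from 0.145 ± 0.164 to 214.4 ± 15.7 CPM, RGI2 from 0.257 ± 0.28 to 148.3 ± 33 CPM and SHH3 from 0.27 ± 0.087 to 144.9 ± 13.7 CPM. These 3 genes had at most 3, 6 and 4 aerobic counts per library, too few for a fold. Of the falls named by the rule, DBP2, an RNA helicase gene, went from 850 ± 85.2 to 6.81 ± 0.506 CPM (log2 −6.96 ± 0.265, adjusted p = 1.98e-09). CYC1, the aerobic cytochrome c isoform, went from 26.3 ± 1.27 to 0.387 ± 0.285 CPM (adjusted p = 2.52e-09), with 2 to 9 counts per hypoxic WT library, too few for a fold. UTR2, YDR222W, YGK1, RPL9A, SCW10, NSR1, HAS1 and SAM1 fell by log2 values between −6.72 and −5.00.

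All 8 tested DAN and TIR genes rose, with a median log2 change of 6.70, and TIR4 reached 3443 ± 286 CPM from 28.1 ± 2.89. Camera called the list (adjusted p = 9.5e-05), and the call was lost with an estimated correlation (adjusted p = 0.32). Of 19 tested PAU genes, a family of near-identical seripauperins, 16 rose and none fell (median 5.64, camera adjusted p = 0.00011; adjusted p = 0.35 with an estimated correlation). The PAU list and the DAN and TIR list overlap, with PAU24 in both, and single PAU values are uncertain because reads may not separate the copies. The summed PAU level went from 30.1 ± 4.81 to 7743 ± 1960 CPM (SD, n = 3). Among hypoxic members of isoform pairs and Rox1 targets 11 of 15 rose and 3 fell (median 2.51, adjusted p = 0.0097; 0.32 as the adjusted p with an estimated correlation), including OLE1, the fatty acid desaturase, at 4.34 and ANB1 at 4.21. Each of the 5 aerobic isoform members fell (median −1.85, adjusted p = 0.013; adjusted p = 0.32 with an estimated correlation), among them HYP2 at −2.43 and COX5A at −1.19. ROX1, the repressor of hypoxic genes, fell by −4.69, and UPC2, a sterol regulator, rose by 2.94.

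In the ribosomal protein list 131 of 132 genes fell and 1 rose (median −3.07, camera adjusted p = 4.1e-29; adjusted p = 0.32 with an estimated correlation). RPS6A went from 944.8 ± 6.04 to 87.6 ± 2.54 CPM and RPL14A from 906.2 ± 36.3 to 63.7 ± 2.1 CPM. For ribosome biogenesis 38 of 39 genes fell and 1 rose (median −3.13, adjusted p = 1.6e-10; adjusted p = 0.38 with an estimated correlation), with NOP1 at −4.47 and GAR1 at −3.93. Histone and G1 or S phase genes fell in 21 of 22 cases, 1 rising (median −1.62, adjusted p = 2.5e-05; adjusted p = 0.32 with an estimated correlation), HTA2 by −3.59. Gcn4-regulated amino acid genes fell in 30 of 40 cases and rose in 7 (median −0.76, adjusted p = 0.0033; adjusted p = 0.50 with an estimated correlation): LEU9 fell by −3.64 and LYS9 rose by 1.95.

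Stress genes controlled by Msn2 and Msn4 rose in 29 of 30 cases and none fell (median 3.06, adjusted p = 1.6e-09; adjusted p = 0.32 with an estimated correlation), GPH1 by 4.16 and GDB1 by 4.49. Peroxisomal and beta-oxidation genes rose in 16 of 18 cases, 1 falling (median 1.82, adjusted p = 0.00083; adjusted p = 0.32 with an estimated correlation), among them POX1 at 6.43 and POT1, which went from 0.415 ± 0.109 CPM (3 to 5 counts per library) to 132.4 ± 12.7 CPM. The tricarboxylic acid and glyoxylate list rose in 18 of 22 genes and fell in 2 (median 1.14, adjusted p = 0.00057; adjusted p = 0.34 with an estimated correlation). Nuclear-encoded respiratory genes rose in 21 of 28 cases and fell in 3 (median 0.79, adjusted p = 0.0034; adjusted p = 0.55 with an estimated correlation): SDH2 rose by 2.21 while NDE1, an external NADH dehydrogenase gene, fell by −4.16. For the ATP synthase 11 of 14 genes rose and none fell (median 0.67, adjusted p = 0.0048; adjusted p = 0.51 with an estimated correlation). Subtelomeric genes rose in 121 of 159 cases and fell in 15 (median 1.26, adjusted p = 4.7e-09; adjusted p = 0.32 with an estimated correlation). The iron regulon rose in 20 of 26 genes and fell in 3 (adjusted p = 0.0059; adjusted p = 0.35 with an estimated correlation), BIO5 by 6.88 and FIT2 by 3.83, while FET3, singled out after its values were seen, fell by −1.82. NAD synthesis rose in 10 of 15 genes and fell in 3 (adjusted p = 0.026; adjusted p = 0.34 with an estimated correlation), BNA2, which overlaps YJR079W, by 5.34. Meiosis and sporulation genes rose in 15 of 23 cases (adjusted p = 0.004; adjusted p = 0.32 with an estimated correlation), SPS100 by 8.39. Oxidative stress defence rose in 18 of 29 genes and fell in 7 (adjusted p = 0.047; adjusted p = 0.66 with an estimated correlation). This call was lost without WT aerobic replicate 3 (adjusted p = 0.051), WT hypoxia replicate 1 (adjusted p = 0.062) or set4∆ hypoxia replicate 3 (adjusted p = 0.05 after rounding).

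Several lists went both ways and were not called. Ergosterol synthesis rose in 15 of 26 genes and fell in 7 (median 0.39, camera adjusted p = 0.23), with ERG28 at 2.03 and HMG1 at −1.85. The sterol uptake list rose in 12 of 21 genes and fell in 5 (adjusted p = 0.12), with the sterol transporter genes AUS1 at 1270 ± 49.2 CPM from 41.8 ± 3.68 and PDR11 at 331.8 ± 16.9 CPM from 20.7 ± 0.626. Hexose transporters rose in 11 of 16 genes and fell in 3 (adjusted p = 0.079), a list that passed without WT aerobic replicate 2 (adjusted p = 0.045) or set4∆ hypoxia replicate 3 (adjusted p = 0.048). Glycolysis and fermentation rose in 7 of 21 and fell in 13 (adjusted p = 0.65), and in that last list the median of −0.38 and the mean of 0.36 had opposite signs.

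EdgeR's quasi-likelihood test called 4971 of the 5924 features, 2503 higher and 2468 lower in WT hypoxia, and 2497 of these changed at least 2-fold, 1229 upward and 1268 downward. The TMM scaling takes most genes as unchanged, although 83.9% of features were called. The balance of rises and falls was also near even with library size alone, at 2594 higher and 2387 lower. Both scalings work on shares of a library, so the balance per cell was not measured. The 3 values of each group did not overlap for 5099 features (86.1%), where chance gives 10%. Camera called 18 of 36 tested lists, 13 higher and 5 lower, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05 and fry, a test of whether a list moves on balance one way, called 33. Adjusted over the list alone, 1 list gained 1 call and none lost any. Oxygen and growth time (8 h against 5.5 h) differed together, so this comparison does not separate them.

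**Figure D2:**
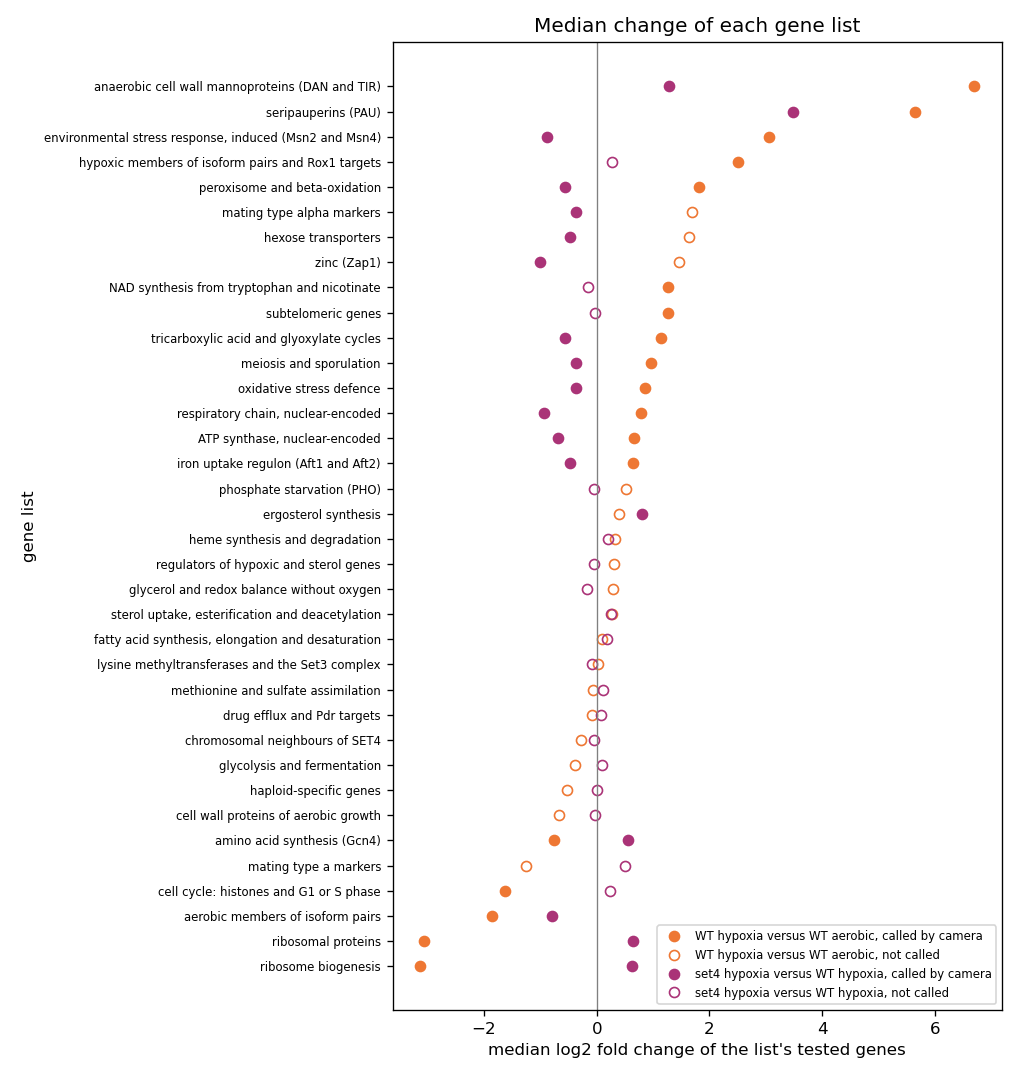
Median log2 fold change of each of the 36 tested gene lists (x axis) in both comparisons, filled where camera called the list with a preset correlation and open where it did not. Ribosomal proteins stand at −3.07 for WT hypoxia against WT aerobic and at 0.64 for set4∆ against WT in hypoxia.

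Without SET4, more of the mRNA of hypoxic cells was for sterol synthesis, anaerobic cell wall proteins and PAU proteins, and less for respiration, stress proteins and iron uptake. Camera called each of these lists with the preset correlation and none with an estimated one (adjusted p = 0.25 to 0.26). YMR317W, a gene near the end of chromosome XIII, rose from 71.3 ± 13 to 1560 ± 106 CPM (SD, n = 3; log2 4.45 ± 0.124 SE, adjusted p = 5.39e-10). DAN4 rose from 230.4 ± 13.9 to 1938 ± 137 CPM (log2 3.07 ± 0.088, adjusted p = 5.39e-10). LEU1, a gene of leucine synthesis, rose from 317.7 ± 114 to 2692 ± 406 CPM (log2 3.08 ± 0.23, adjusted p = 4.39e-06). YHB1, the flavohaemoglobin gene, rose from 105.1 ± 5.08 to 530.2 ± 44.2 CPM (log2 2.33 ± 0.082, adjusted p = 2.13e-09). OAC1, YJL213W, BAT1, YMR316C-A, HUG1 and CHA1 were the other rises named by the rule, at log2 2.08 to 2.80, and YMR316C-A overlaps DIA1, so its reads are uncertain. After SET4 itself the falls named by the rule were SPS100, from 1750 ± 256 to 107.7 ± 47.8 CPM (log2 −4.02 ± 0.316, adjusted p = 5.72e-06), and GRE1 at −3.42, YOR387C at −3.23, HXT5 at −3.08, LYS20 at −2.95, SSA3 at −2.91, YCL048W-A at −2.77 and CRC1 at −2.75. FET3, the iron multicopper oxidase gene, fell from 241.5 ± 34.3 to 36.3 ± 9.2 CPM (log2 −2.73).

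Ergosterol synthesis genes rose in 25 of 26 cases and none fell (median 0.81, camera adjusted p = 1.4e-11; adjusted p = 0.26 with an estimated correlation). ERG11, the target of azole drugs, rose from 1204 ± 114 to 3668 ± 172 CPM (log2 1.61 ± 0.085), ERG1 by 1.64 and ERG4 by 1.63. The sterol uptake list was not called (10 of 21 higher, 4 lower, adjusted p = 0.16), although AUS1 rose by 1.05. All 8 DAN and TIR genes rose (median 1.28, adjusted p = 2.4e-05; adjusted p = 0.25 with an estimated correlation), with TIR1 at 2985 ± 638 and 8023 ± 470 CPM. Of 19 PAU genes 18 rose and none fell (median 3.49, adjusted p = 4e-10; adjusted p = 0.25 with an estimated correlation), and their summed level went from 7743 ± 1960 to 28420 ± 4610 CPM (SD, n = 3). HEM13, a heme synthesis gene expressed without oxygen, rose by 1.58, and the hypoxic isoform list was not called (8 of 15 higher, 5 lower, adjusted p = 0.24). Of the aerobic isoform members 3 of 5 fell, COX5A by −1.32, PET9 by −0.80 and HYP2 by −0.75 (adjusted p = 0.027; adjusted p = 0.25 with an estimated correlation). This list call was lost with only the 6 hypoxic libraries (adjusted p = 0.054) and without set4∆ hypoxia replicate 1 (adjusted p = 0.056).

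Nuclear-encoded respiratory chain genes fell in 27 of 28 cases (median −0.93, adjusted p = 6e-14; adjusted p = 0.25 with an estimated correlation), COX4 by −1.38 and QCR7 by −1.35. All 14 ATP synthase genes fell (median −0.69, adjusted p = 3.4e-08; adjusted p = 0.25 with an estimated correlation), ATP4 from 365.5 ± 13.4 to 205.3 ± 8.26 CPM. In the tricarboxylic acid list 15 of 22 genes fell and 1 rose (median −0.57, adjusted p = 1.6e-05; adjusted p = 0.25 with an estimated correlation), MLS1 by −2.28. Peroxisomal genes fell in 14 of 18 cases (median −0.57, adjusted p = 6e-06; adjusted p = 0.25 with an estimated correlation), POT1 by −1.75. The iron regulon fell in 16 of 26 genes (median −0.47, adjusted p = 5.5e-06; adjusted p = 0.25 with an estimated correlation), FIT2 by −2.03. Stress genes fell in 27 of 30 cases (median −0.88, adjusted p = 7.8e-11; adjusted p = 0.25 with an estimated correlation), and HSP26 went from 23050 ± 608 to 10550 ± 1460 CPM. Zinc-regulated genes fell in 10 of 13 cases, 1 rising (adjusted p = 0.0013; adjusted p = 0.43 with an estimated correlation), ADH4 by −2.48. Hexose transporters fell in 8 of 16 cases, 1 rising (adjusted p = 0.027; adjusted p = 0.25 with an estimated correlation), and meiosis genes in 12 of 23, 2 rising (adjusted p = 0.016; adjusted p = 0.26 with an estimated correlation). Oxidative stress defence fell in 19 of 29 genes and rose in 7 (adjusted p = 0.0038; adjusted p = 0.49 with an estimated correlation): GRX2, which overlaps EMI1, fell by −1.15, while YHB1 was among those that rose. Alpha mating markers fell in 2 of 3 cases (adjusted p = 0.047; adjusted p = 0.38 with an estimated correlation). That call was lost with RLE factors, no filter, a stricter filter or a replicate block (adjusted p = 0.053, 0.056, 0.052 and 0.055). It was also lost without WT aerobic replicate 1, WT hypoxia replicate 1 or 3, or any 1 set4∆ library (adjusted p = 0.05 to 0.062).

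Ribosomal protein genes rose in 119 of 132 cases and none fell (median 0.64, adjusted p = 8e-24; adjusted p = 0.25 with an estimated correlation). RPL3 stood at 5725 ± 229 CPM in aerobic cells, 522.1 ± 34.7 in WT hypoxia and 1194 ± 109 in set4∆ hypoxia. Ribosome biogenesis rose in 30 of 39 genes (median 0.62, adjusted p = 7.9e-07; adjusted p = 0.49 with an estimated correlation), NOP1 by 1.09. Gcn4-regulated genes rose in 31 of 40 cases and fell in 8 (median 0.55, adjusted p = 2.3e-05; adjusted p = 0.33 with an estimated correlation): HIS1 rose by 1.14 and LEU9 by 1.23, while LYS9 fell by −1.86 and LYS20 by −2.95. The subtelomeric list was not called (35 higher, 44 lower of 159, adjusted p = 0.73), and its median of −0.03 and mean of 0.28 had opposite signs. That list holds PAU genes, and its highest log2 change, 6.17, is also the highest of the PAU list. Its 145 members outside the PAU, DAN and TIR lists had a median of −0.09.

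The quasi-likelihood test of edgeR called 3169 features in set4∆ against WT, 1720 higher and 1449 lower (1490 higher and 1583 lower with the 6 hypoxic libraries alone), and 458 changed at least 2-fold, 145 upward and 313 downward. The groups did not overlap for 3670 features (62%), where chance gives 10%. Camera called 18 of 36 lists, 6 higher and 12 lower, and 0 with an estimated correlation, where 6 lists had an unadjusted p under 0.05 and fry called 28. Adjusted over the list alone, 12 lists gained at most 2 calls and none lost any. Genotype and culture differ together between the groups, and growth density per culture was not used here.

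**Figure D3:**
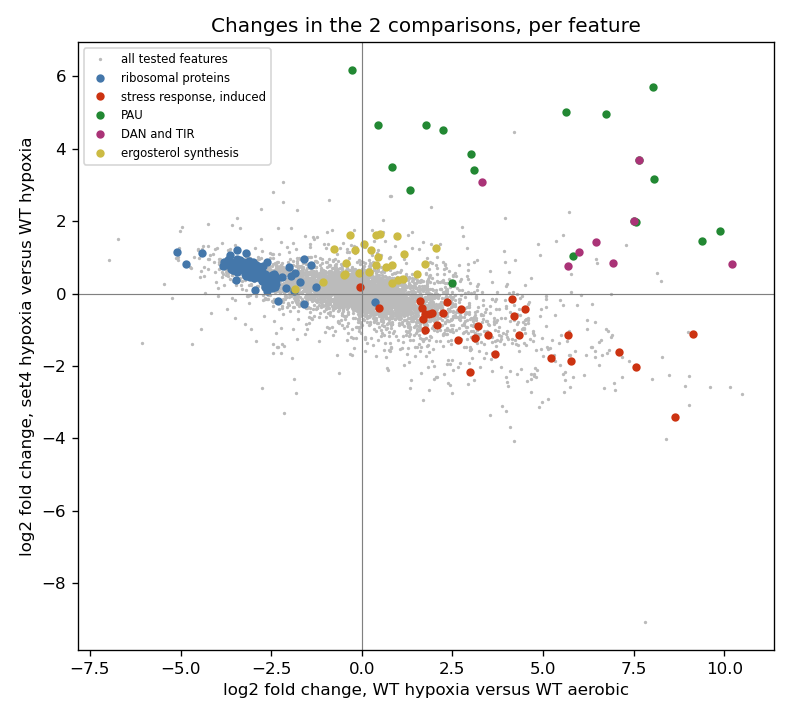
Log2 fold change of each tested feature in WT hypoxia against WT aerobic (x axis) and in set4∆ against WT hypoxia (y axis), with 5 gene lists in colour. Most ribosomal protein genes lie at upper left, most stress genes at lower right, and the DAN and TIR genes at upper right with 16 of the 19 PAU genes called higher on the x axis and 18 on the y axis.

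Genes that changed in both comparisons mostly changed in opposite directions. Of 2816 features called in both, 2330 (82.7%) moved in opposite directions and 486 in the same. Features higher under hypoxia and lower in set4∆ numbered 1127, where independent lists would give 612, and features lower under hypoxia and higher in set4∆ 1203, where they would give 717. The same-direction overlaps were 318 (727 for independent lists) upward and 168 (604) downward. DAN1, TIR1, ERG11 and AUS1, picked here as examples after their values were seen, were higher in both, whereas HSP26, FIT2 and POT1 were higher under hypoxia and lower in set4∆. The WT hypoxia libraries enter both comparisons with opposite sign, and 20 simulated sets of unchanged groups gave correlations across genes with a median of −0.48 (−0.54 to −0.41) where the data gave −0.48, with Spearman's rho at −0.55. The observed covariance was −0.533 and the simulated median −0.012 (−0.016 to −0.01), a difference of −0.522. In the simulated sets 0 features were called in both comparisons, in opposite or in the same direction. All groups in these sets were unchanged, so the threshold leaves few calls in either comparison. A real hypoxia change beside an unchanged set4∆ group was not simulated. The 0 therefore does not show how many joint calls the shared libraries would give in that case. Genes are not independent replicates, and 3 shared libraries cannot be divided into parts of at least 2. A shift common to the WT hypoxia cultures was not simulated, so part of the excess over independent lists may still come from the shared controls.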

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

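The overlap counts with library size alone, limma-voom and the likelihood ratio test (2344, 2306 and 2368 features opposite in direction, against 2330) were chosen after seeing the data. No count of genes moved by over 1.5 times under any alternative run. With each library left out in turn, WT hypoxia against WT aerobic gave 4826 to 5029 features, 2486 to 2561 of at least 2-fold and 17 to 20 lists, and set4∆ against WT hypoxia gave 2713 to 3206, 433 to 525 and 16 to 18. The opposite overlap ranged from 2020 to 2397 and the SET4 change from −9.19 to −8.91. With the inter-gene correlation estimated, 0 lists were called in either comparison in place of 18, with 3 and 6 at an unadjusted p under 0.05, and fry called 33 and 28. Camera and fry differ by construction, since fry does not compare a list with other genes. Glycolysis under hypoxia (fry adjusted p = 0.002) and subtelomeric genes in set4∆ (fry adjusted p = 0.03) had the opposite direction from camera, which called neither; the cause was not tested. Among single named genes, leaving out a library ended 9 calls in set4∆, all of them MFA1 or GSM1, and no call under hypoxia. Whether replicate numbers pair the libraries in part stays open. Deviations of same-numbered libraries correlated at −0.14 to 0.26, and 5 of 9 pairs were over 0.1. Of the 9 libraries, 4 correlated best with their own number in both other groups. With a replicate block the counts were 5037 and 3347 features, 2498 and 461 of at least 2-fold, 18 and 17 lists and an opposite overlap of 2464, and 4960 of the 4971 and 3141 of the 3169 calls were shared with the fit without the block. In set4∆ with the block, the alpha marker list was not called (adjusted p = 0.055) and SAG1 passed (−0.14, adjusted p = 0.0479). Library size alone moved the share of higher calls in set4∆ from 54.3 to 61% and the median of all genes to 0.077. The fit of the 6 hypoxic libraries alone turned that balance, with 1490 higher and 1583 lower in place of 1720 and 1449, and no filter left it near even at 1569 and 1545; the cause was not tested. Under hypoxia the 2-fold calls, 1229 higher and 1268 lower, turned to 1270 and 1227 with library size alone and to 1264 and 1263 without set4∆ hypoxia replicate 2. At these depths, genes with few counts in 1 group, such as YCL048W-A, RGI2, SHH3 and POT1 in aerobic cells and CYC1 in hypoxic cells, have no firm fold.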

Other observations

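Of the tests in this part, those on the reversal, on the PAU genes and on leucine and lysine genes were chosen after the results were seen, as were the leucine and lysine lists themselves. Several lists were called by camera in neither comparison although single members moved far. Among cell wall proteins of aerobic growth, 10 of 25 rose and 15 fell under hypoxia (camera adjusted p = 0.43), with GSC2, a glucan synthase gene, at 4.27 and UTR2 at −6.72. In set4∆ 9 rose and 10 fell (adjusted p = 0.54), and SCW4 went from 465.1 ± 40.9 to 1524 ± 75.2 CPM (SD, n = 3) and TIP1 from 3721 ± 448 to 976.6 ± 135. Fatty acid genes went both ways too, with 8 of 18 higher and 8 lower under hypoxia (adjusted p = 0.93) and 8 higher and 6 lower in set4∆ (adjusted p = 0.73). ELO3, a fatty acid elongase gene, rose by 1.82 in set4∆, and SCS7, a sphingolipid hydroxylase gene, fell by −1.49. The heme list had 6 of 11 higher and 4 lower under hypoxia (adjusted p = 0.55) and 6 higher and 0 lower in set4∆ (camera adjusted p = 0.056), where HEM14, which overlaps BUD25, rose from 242.6 ± 15.5 to 387.6 ± 15.9 CPM. In set4∆ that list passed with no filter (adjusted p = 0.043) and without WT hypoxia replicate 1 (adjusted p = 0.021) or set4∆ hypoxia replicate 2 (adjusted p = 0.037). Methionine and sulfur genes were 10 of 28 higher and 13 lower under hypoxia (adjusted p = 0.64), SAM2 at −2.78, and 11 higher and 4 lower in set4∆ (adjusted p = 0.22), SAM2 at 1.52.

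The list of regulators of hypoxic and sterol genes had 11 of 19 members higher and 7 lower under hypoxia (adjusted p = 0.44) and 5 higher and 7 lower in set4∆ (adjusted p = 0.73), where SUT1 rose by 1.14 and HAP2 fell by −0.61. SET4 itself belongs to this list and to the next and entered their tests, as 1 of the higher members under hypoxia and, through the deletion, 1 of the lower in set4∆. For methyltransferases and the Set3 complex the counts were 8 and 11 of 24 under hypoxia (adjusted p = 0.93) and 4 and 9 in set4∆ (adjusted p = 0.29), with SET2 at −2.02 under hypoxia. Drug efflux genes were 9 higher and 9 lower of 19 under hypoxia (median −0.09, mean 0.48, adjusted p = 0.90) and 7 and 5 in set4∆ (median 0.08, mean −0.01, adjusted p = 0.88), where RSB1 fell by −2.31. Glycerol and redox genes were 10 and 5 of 19 under hypoxia (adjusted p = 0.44), GPP1 at −2.81, and 8 and 7 in set4∆ (adjusted p = 0.70). Phosphate genes were 11 and 9 of 21 (adjusted p = 0.78), PHO3 at −3.77, and 5 and 5 (adjusted p = 0.82). Haploid-specific genes were 4 and 5 of 9 (adjusted p = 0.66) and 2 and 2 (adjusted p = 0.88), FAR1 rising by 1.55 in set4∆. Zinc genes were 10 and 3 of 13 under hypoxia (adjusted p = 0.095, and 0.044 in the fit of its 6 libraries), ZAP1 at 3.46. In set4∆, glycolysis had 7 of 21 higher and 6 lower (adjusted p = 0.97), HXK2 at 1.10, NAD synthesis 3 and 8 of 15 (adjusted p = 0.41), and histone and G1 or S phase genes 6 and 4 of 22 (adjusted p = 0.73). Of 48 tested transposon features, near-identical copies, 34 rose and 5 fell under hypoxia (median 1.07) and 5 rose and 4 fell in set4∆ (median 0.07).

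In set4∆, the stress and respiratory lists fell and the ribosomal list rose, each against its direction under hypoxia in WT (adjusted p = 0.25 for each with an estimated correlation, and 0.32, 0.55 and 0.32 under hypoxia). Replicate noise in the shared WT hypoxia libraries, drawn for each gene on its own, does not account for the covariance over all genes. The covariance of the comparisons was −0.533, and simulated unchanged groups, which held such noise alone, gave −0.016 to −0.01. Noise shared by the genes of a list was not simulated, so these values do not test the lists themselves. A shift common to all 3 WT hypoxia cultures would enter both comparisons with opposite sign and was not simulated. Less complete hypoxia argues for lower DAN and TIR genes, whose median was higher by 1.28 (SD of members 1.11), although loss of SET4 could itself raise them. A different growth state of the set4∆ cultures stays open. The stress list means of their 3 libraries ranged over 0.4 log2 units against 0.07 in WT hypoxia. A spread within a group cannot show why its mean differs from that of the other group. With genotype and culture confounded, growth state and loss of SET4 cannot be told apart.

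The PAU family was higher in set4∆. Reads moving between copies would leave the sum unchanged, and the log2 ratio of summed CPM was 1.88, with the lowest set4∆ library at 23150 and the highest WT hypoxia library at 9948. A rise of all genes near chromosome ends is argued against by the 145 other subtelomeric genes, whose median was −0.09 (SD 0.82) against 3.49 for PAU genes, and leaving out any 1 hypoxic library left a log2 ratio of at least 1.74. Loss of SET4, direct or indirect, stays open as a biological explanation and was not tested apart from the group difference itself.

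Leucine and Leu3-regulated genes (11 of 11) were higher in set4∆ with a median of 1.29, and 7 of 8 lysine genes lower and 1 higher with a median of −0.50. A restored LEU2, URA3 or MET17 or a lost LYS2 is argued against by 0 counts of the first 3 in the set4∆ libraries and at least 2105 counts of LYS2, while a marker from another species was not tested. The change may be part of the wider reversal: under hypoxia the leucine genes had a median of −1.61 and the lysine genes 0.64, and set4∆ minus WT aerobic gave 0.35 (SD 1.01) and 0.08 (SD 0.57), so that this stays open. By edgeR, 5 of the 11 leucine genes lay above their aerobic level, 3 below it and 3 did not pass, with GDH1 at 1.13 and LEU9 at −2.42, and 3 of the 8 lysine genes lay above, 3 below and 2 did not pass, with LYS20 at −1.26.

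A further hypothesis was that loss of SET4 acts on chromosomal neighbourhoods. The rank correlation of the log2 fold changes of 5668 pairs of neighbouring genes was 0.098, above 1000 permutations (−0.051 to 0.046), but the hypoxia comparison gave 0.122, so the data do not single out set4∆. The margin for that reading was chosen after the value was seen.

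With 3 libraries against 3, the 6 libraries can be split in 10 ways, too few for a share under 0.05. For the genes changed, those changed at least 2-fold and the opposite overlap, 1 split of 10, the real one, gave as many (4971, 2497, 3169, 458 and 2330). The highest of the others was 0 by edgeR, with 2 to 32 and 25 to 263 features at an unadjusted p under 0.05. Each of these other splits mixes libraries of both groups on each side, so the real difference widens the spread within its groups. Few calls follow from that mixing, so these splits do not show what unchanged groups would give. For the lists called, 3 splits of 10 gave at least the real 18 under hypoxia (highest other 19). In set4∆ 2 of 10 did (highest other 18). The number of lists called thus did not set the real grouping apart from these splits. Their sides hold unequal numbers of each group, so part of the real difference remains between them. For lists too, these splits cannot show what unchanged groups would give.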
